A study of Homo sapiens with 15 samples.

How the data were processed

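Total RNA from BT474, a human breast cancer cell line with HER2 amplification, and from 4 clones selected from it for resistance to trastuzumab emtansine (T-DM1, an antibody against HER2 that carries a microtubule poison) was measured on 15 Affymetrix gene arrays. Per the labels' protocols, the clones came from single cells after long exposure to T-DM1 and were kept in 5 nM of the drug for 3 months; whether the drug was present at harvest is not stated. Each of the 5 groups (parental, clone 1, clone 2, clone 3 and clone 6) had 3 arrays, which the labels call biological replicates.

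The authors deposited log2 expression values for 53617 probe sets in each array. Per the submitters' processing notes, the tools were RMA, Affymetrix Expression Console 1.4.1 and the Transcriptome Analysis Console; which step each tool did is not given in the sources used here. RMA subtracts background, makes the intensity distributions of the arrays alike and summarises the probes of a set on the log2 scale, so a shift of most genes in one direction would be largely removed and small changes are compressed near the background. After this, the upper quartile of the parental arrays still lay between 5.94 and 5.96 and that of the clone arrays between 5.80 and 5.89, on the log2 scale. No 2 columns were identical.

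Gene symbols came from the platform annotation supplied with the values, matched through gene identifiers to the RefSeq gene table of assembly GRCh38, which was used for names and gene order and not for coordinates, since the build behind the probe sets is not given in the sources used here. Of the probe sets, 16098 (30.0%) had 1 symbol, 0 had several and 37519 had none here; the last were not tested as genes. Probe sets above the 40th percentile of their own array in at least 3 arrays were kept, and where a symbol had several probe sets (779 symbols) the one with the highest mean over all 15 arrays stood for the gene. This left 12147 genes, of which 10391 code for proteins. ERBB2, the tubulins, the vacuolar ATPase subunits, the listed drug efflux pumps, CAV1 and SLC46A3 had no symbol here and were not analysed here. The only tested member of the drug efflux list was MVP, the major vault protein.

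A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 residual degrees of freedom before moderation), so that all comparisons share 1 estimate of the spread. Each clone was compared with the parental line and with each other clone, and an F test asked which genes differed among the 4 clones. A gene was called at an adjusted p (Benjamini-Hochberg, within each comparison) below 0.05, and counts with an added limit of 2-fold are given as well. All adjusted p-values for single genes are limma's. For 35 gene lists, 30 of which had at least 5 measured genes, limma's camera with a preset correlation of 0.01 compared the list with all other genes. The list members called are counted after adjustment over all genes tested and again adjusted over the list alone.

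The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes up to 15 genes higher and 15 lower in all 4 clones with every clone array beyond every parental array, ranked by their smallest change over the clones. It adds up to 10 higher and 10 lower genes per clone whose 3 arrays all lie beyond the parental ones, up to 5 higher and 5 lower genes that set 1 clone apart from the parental line and from the other 3 clones, up to 4 called members per list, and 20 fixed genes linked to HER2, lysosomes, drug efflux and cell division. Genes without a symbol of their own were counted and not described.

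The steps were tested on simulated data drawn for the 12147 genes from the parental means and the observed spread within groups, with 200 genes changed by 1.5, 2 or 4 times and 5 runs per comparison. For clone 1 against parental, 0.633 of the 1.5-fold, 0.931 of the 2-fold and 1.00 of the 4-fold changes were recovered, and 0.0584 of the calls were false. For clone 1 against clone 2, drawn with the spread of these clones alone, the recovered shares were 0.537, 0.907 and 0.988.

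Comparisons that share the parental arrays share their chance errors, so 50 simulations of 4 unchanged clones against the same controls are given beside overlaps and correlations. The alternatives were no filter and a stricter filter on dim probe sets, renewed quantile normalization, centring on array medians, the replicate number as a block, leaving out each array, a fit to the 6 arrays of a comparison, eBayes with trend and robust settings, array weights, the mean of all probe sets of a gene, a stricter adjusted p, camera with an estimated correlation, and limma's fry. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.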

Results

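The data comprise 15 arrays, 3 each from parental BT474 cells and from the T-DM1-resistant clones 1, 2, 3 and 6. They address which genes differ between each resistant clone and the parental line. No clone without selection or without the drug culture was measured. Resistance, single-cell cloning and long culture with the drug therefore cannot be told apart. A difference in culture or array processing between the parental line and the clones could not be separated from them either. The 3 arrays of a clone replicate that clone only. The upper quartiles of the arrays lay between 5.80 and 5.96 on the log2 scale. Correlations across probe sets, which are not independent replicates, ranged from 0.985 to 0.993 between arrays of 1 group and from 0.975 to 0.991 between arrays of different groups. The first principal component of the tested genes held 25.4% of the variance and the second 23.8%. Arrays of clones 1 and 2 lay together, whereas those of clone 3, clone 6 and the parental line formed a cluster each.

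**Figure D1:**
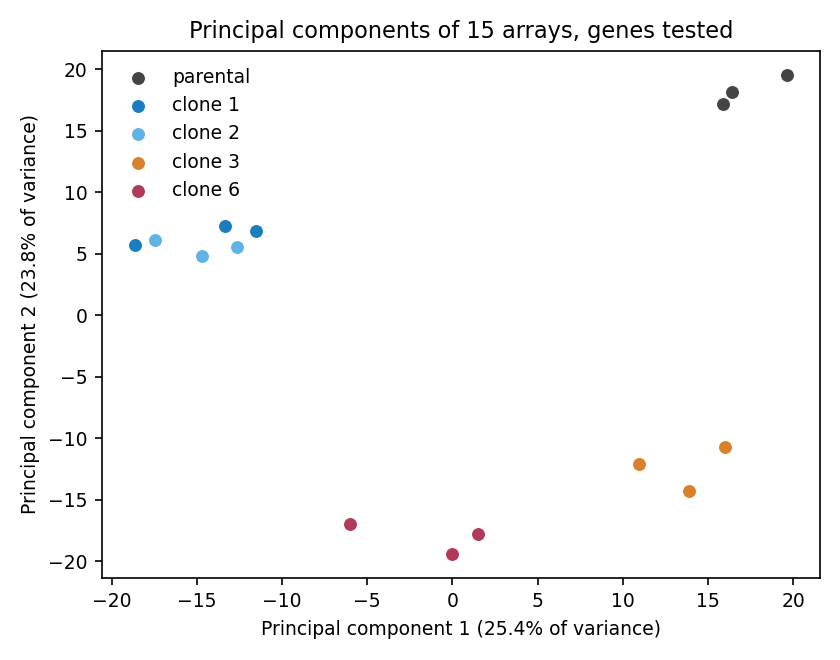
Each point is 1 array, placed by the first principal component (25.4% of the variance) and the second (23.8%) of the 12147 tested genes and coloured by group. The 3 arrays of each group lie close together, and the arrays of clones 1 and 2 overlap.

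All 4 clones had much lower NPY1R, a receptor for neuropeptide Y, and much higher CXCR4, the receptor for the chemokine CXCL12. NPY1R was 9.25 ± 0.29 (SD, n = 3, log2) in parental cells and changed by -3.88 to -3.11 in the clones, a fall of 8.63- to 14.7-fold (SE 0.18, highest adjusted p = 1.91e-08). CXCR4 was 7.49 ± 0.09 in parental cells and rose by 1.92 to 2.23, or 3.78- to 4.70-fold (SE 0.15, highest adjusted p = 5.58e-07). With them fell FSTL5, NRK (a kinase), MBNL3 (a splicing regulator), GPC6 (a cell surface proteoglycan), MME (neprilysin, a peptidase of the cell surface) and FZD8 (a Wnt receptor). FSTL5 changed by nearly the same amount in each clone, between -2.90 and -2.72 (SE 0.12). Among the genes that rose were KLK12, a secreted protease, by 1.64 to 2.54 (SE 0.38), CLCA2 by 1.30 to 2.79 (SE 0.20), NCKAP5 by 1.15 to 1.42 (SE 0.14) and MVP, the major vault protein, by 1.00 to 1.35 (SE 0.14).

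The remaining genes named as higher in all 4 clones were SCARNA6, CASC15, MIR30A, GPR155, MCM6, GPX2, ABHD11, FFAR2, PLEK2 and STX8, with changes between 0.77 (STX8, clone 3) and 1.53 (GPX2, clone 6). Those named as lower were ANTXR1, PM20D2, PTCHD1, GXYLT2, ADGRL2, MIR4653, MIR3671 and TMEM117, between -1.15 (TMEM117, clone 1) and -2.64 (PTCHD1, clone 2). A dimmer probe set of PTCHD1 changed by -0.12 to -0.34. The calls of ABHD11 were lost in clones 1 and 2 when any of 10 arrays was left out in turn (log2 change 0.43 to 0.95, adjusted p up to 0.212), in clone 3 for 3 arrays (0.81 to 1.03) and in clone 6 for 2 arrays (0.87 to 0.96). The calls of GPX2 in clones 1 and 2 were lost without parental replicate 3 or without replicate 2 of the clone concerned (0.61 to 0.78). That of MCM6 was lost in clone 1 without its replicate 3 (0.74) and in clone 2 without its replicate 3, parental replicate 2 or parental replicate 3 (0.70 to 0.80).

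**Figure D2:**
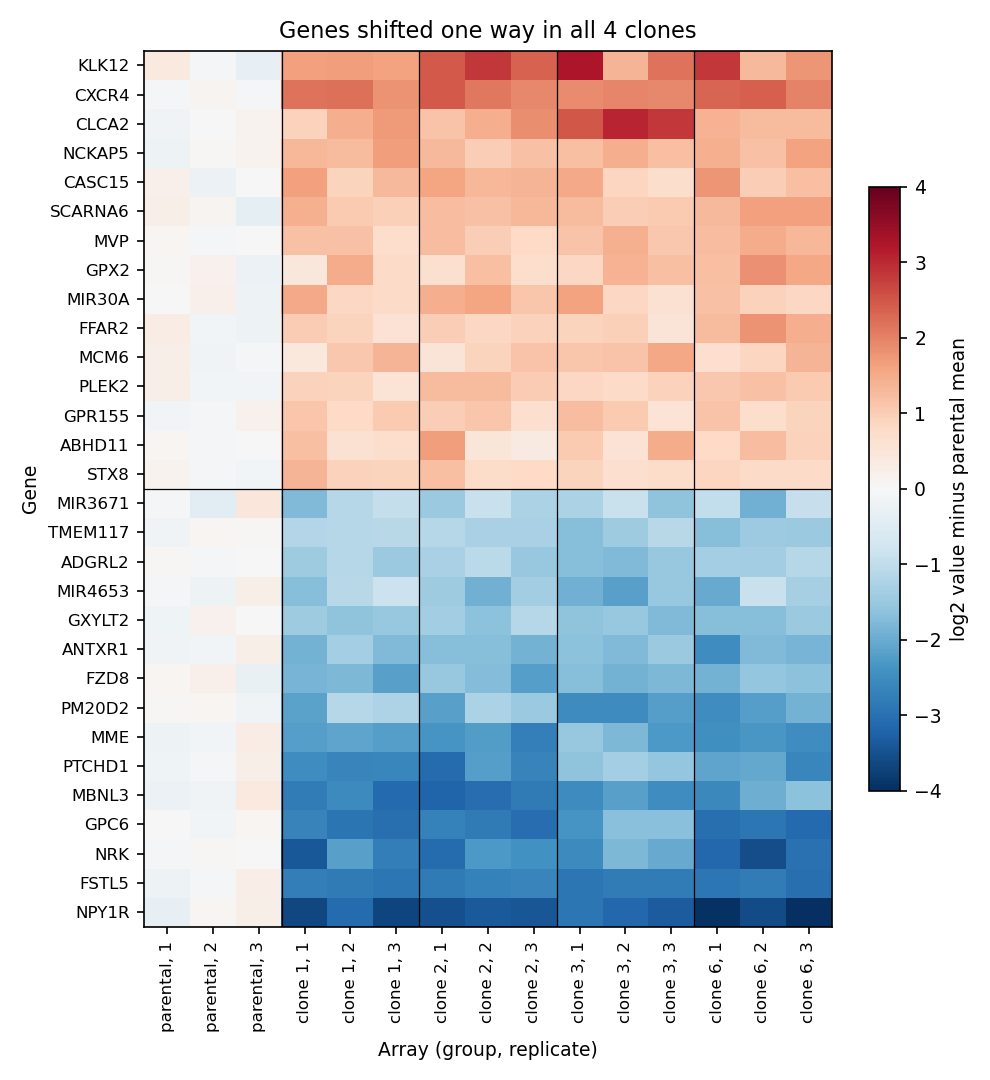
Colours give the log2 value of each array (columns, grouped by cell line) minus the parental mean for the 15 genes higher (top) and 15 lower (bottom) in all 4 clones. CXCR4 lies 1.92 to 2.23 above and NPY1R lies -3.88 to -3.11 from it, as means over the 3 arrays of each clone.

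In total 126 genes rose and 443 fell in all 4 clones, against 0.193 and 2.52 for independent lists of the same sizes. Those products ignore the shared parental arrays. The simulated unchanged clones had 0 such genes, but at most 2 genes were called in any of them. They therefore do not show how far shared controls raise the overlap of clones that do change. With renewed quantile normalization 196 rose and 306 fell in all 4 clones. Centring on array medians gave 99 and 466, so the size of the imbalance depends on the scaling. At least 2-fold, 7 rose and 24 fell. At least 1 clone changed 4550 of the 12147 genes, and 152 rose in 1 clone and fell in another. Across genes, which are not independent replicates, the log2 changes of clones 1 and 2 correlated at 0.883, those of the other pairs at 0.484 to 0.691, and those simulated with no effect at 0.499. The covariances were 0.0518 to 0.0959, against 0.0113 from the shared controls alone. The 3 parental arrays, too few to give each of the 4 clones its own, were not split between the clones of a pair either.

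In clone 1, CEACAM5, a cell adhesion protein of epithelia, rose 7.97-fold from 8.44 ± 0.22 to 11.44 ± 0.09 (log2, SD, n = 3, adjusted p = 3.03e-09), and GATA3, a transcription factor of luminal breast cells, fell 7.41-fold from 9.12 ± 0.13 to 6.23 ± 0.21 (adjusted p = 3.03e-09). NTSR1, the neurotensin receptor, rose by 2.14 (SE 0.17), YPEL2 by 1.88 (SE 0.15) and CEACAM6 by 1.56. NPR3, which clears natriuretic peptides, fell by 2.31 (SE 0.14) and NCAM2, a cell adhesion gene, by 2.63. Altogether 733 genes rose and 1359 fell, 48 and 97 of them at least 2-fold. With renewed quantile normalization 971 rose and 1056 fell, while with arrays centred on their median 647 rose and 1391 fell. The excess of lower genes thus depends on the scaling. With renewed quantile normalization 52.1%, 52.2%, 50.3% and 49.7% of the calls in clones 1, 2, 3 and 6 were lower, so clone 6 had no excess. Centring kept an excess in clones 2, 3 and 6 too, where 72.6%, 67.9% and 69.1% of the calls were lower. The total of 2092 dropped to 1229 without parental replicate 3 and reached 3448 with array weights.

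Clone 2 had much the same leading genes. GATA3 fell 8.83-fold (log2 change -3.14, SE 0.15, adjusted p = 1.22e-09), CEACAM5 rose 6.58-fold (2.72, SE 0.15), NTSR1 rose by 2.10 (SE 0.17) and NPR3 fell by 2.15 (SE 0.14). DKK1, a secreted Wnt inhibitor, fell by 2.22, CD68, a lysosomal glycoprotein, rose by 1.89, and AXL, a receptor tyrosine kinase, rose by 0.97 (SE 0.11). Altogether 664 genes rose and 1394 fell, 50 and 117 at least 2-fold, against 949 and 1037 with renewed quantile normalization. The total of 2058 dropped to 1265 without parental replicate 3.

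Clone 3 differed in several of these genes. CEACAM5 fell 2.48-fold from 8.44 ± 0.22 to 7.13 ± 0.34 (adjusted p = 2.48e-05) and GATA3 fell 1.70-fold (log2 change -0.76, SE 0.15, adjusted p = 0.00183). FAR2, which makes fatty alcohols, fell 7.45-fold (-2.90, SE 0.13), TMTC1 fell 7.92-fold (-2.99, SE 0.15), POGLUT3 fell by 2.44 (SE 0.13), ASS1, an enzyme of arginine synthesis, by 2.20 and TSPAN3 by 1.83 (0.0856 in a dimmer probe set). TARP rose by 2.67 (SE 0.36), CLCA2 by 2.79 and MX2, an interferon-induced gene, by 1.55. Altogether 756 genes rose and 1334 fell, 41 and 123 at least 2-fold, against 1032 and 1046 with renewed quantile normalization. The total of 2090 dropped to 1368 without parental replicate 2 and 1275 without parental replicate 3.

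Clone 6 shared high CEACAM5 with clones 1 and 2 and low FAR2 with clone 3. CEACAM5 rose 8.15-fold (log2 change 3.03, SE 0.15), FAR2 fell 11.2-fold (-3.48, SE 0.13, adjusted p = 5.47e-11), GATA3 fell 5.12-fold (-2.36) and CFL2, an actin-binding protein, fell 6.64-fold (-2.73, SE 0.19). PAPSS2, which makes the sulfate donor of the cell, rose from 6.47 ± 0.01 to 8.91 ± 0.02 (adjusted p = 2.90e-09), MGP rose by 2.25 (SE 0.16), IQGAP2 by 2.49 and LRP2 by 2.54. DSG2, a desmosomal cadherin, fell by 2.09 (SE 0.15), CD47 by 1.76 (SE 0.10) and TNC by 1.49. Altogether 939 genes rose and 1785 fell, 72 and 194 at least 2-fold, against 1330 and 1314 with renewed quantile normalization.

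Genes of mitosis and the spindle checkpoint were lower in clones 3 and 6, and 4 of them fell in all 4 clones. Of 41 measured members, 16 fell and 0 rose in clone 3 (18 and 0 adjusted over the list alone), with a median log2 change of -0.34, and 25 fell and 0 rose in clone 6 (29 and 0 adjusted over the list alone), with a median of -0.51. CCNB2 fell by 1.00 in clone 3 and 0.95 in clone 6 (SE 0.11), KIF18A by 0.86 and 1.05, CDC20 by 0.62 and 1.18, and the fixed genes PLK1 by 0.79 and 0.70 and CCNB1 by 0.78 and 0.92. In clones 1 and 2, where 7 and 5 members fell and 1 rose in each (7 and 3 fell and 1 and 0 rose adjusted over the list alone), CDC20 fell by 0.64 and 0.42, CCNB1 by 0.36 in each, and PLK1 by 0.43 in clone 1. Of these calls, that of CDC20 in clone 2 was lost without any 1 of 11 arrays (-0.47 to -0.28) and with the replicate number as a block (adjusted p = 0.0513), those of CCNB1 without any 1 of 4 (-0.38 to -0.29) and that of PLK1 without any 1 of 6 (-0.49 to -0.34), parental replicate 2 among them each time. The mean of the list was -0.35 ± 0.08 (SD, n = 3) relative to parental in clone 3, -0.50 ± 0.13 in clone 6, -0.06 ± 0.14 in clone 1 and -0.06 ± 0.21 in clone 2. Camera called the list in clone 3 (adjusted p = 1.64e-06) and clone 6 (adjusted p = 7.89e-10); with an estimated correlation the adjusted p was 0.951 and 0.679. Of 25 genes of DNA replication and S phase, 1 rose (MCM6) and 1 fell (MCM4) in clone 3, and 1 rose (MCM6) and 0 fell in clone 6 (1 and 0 in each, adjusted over the list alone). The call of MCM4 (-0.56) was lost without any 1 of 8 arrays.

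Luminal genes moved both ways. Of 26 members of the oestrogen receptor and luminal list, 8, 7, 11 and 10 fell in clones 1, 2, 3 and 6 and 2 rose in each (9, 9, 12 and 12 fell and 3, 5, 2 and 2 rose adjusted over the list alone). ESR1, the oestrogen receptor, fell by 0.84, 0.61, 0.43 and 0.55 (SE 0.14), and its call in clone 3 was lost when any of 8 arrays was left out (-0.36 to -0.48). PGR, the progesterone receptor, fell by 1.28, 0.97 and 1.43 in clones 1, 2 and 3 (SE 0.28), and its call in clone 2 was lost without any 1 of 4 arrays, parental replicate 3 among them (-0.96 to -0.88). By contrast, TFF1, a secreted product of an oestrogen target gene, rose by 0.70, 1.16, 0.58 and 1.51 (SE 0.14). Camera called the list in clone 3 alone (median -0.37, adjusted p = 0.0496; 0.951 as adjusted p with an estimated correlation and 0.0680 with the replicate number as a block), while in clone 1 the adjusted p was 0.0629, and clones 1 and 3 were not called different for it.

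Of 18 genes of cholesterol biosynthesis, 6 rose and 2 fell in clone 3 (9 and 2 adjusted over the list alone; median 0.26, adjusted p = 0.0496) and 7 rose and 0 fell in clone 6 (9 and 0 adjusted over the list alone; median 0.20, adjusted p = 0.0256). The adjusted p with an estimated correlation was 0.951 and 0.679. MVD, an enzyme of the mevalonate pathway, rose by 0.91 and 0.71 (SE 0.14), whereas SREBF2, a regulator of the pathway, fell by 0.60 in clone 3 and 0.39 in clone 2, where its call was lost without any 1 of 5 arrays, each parental array among them (-0.42 to -0.30). In the BCL2 family and death receptor list, 7 of 17 genes fell and 0 rose in clone 3 (9 and 1 adjusted over the list alone; median -0.34, adjusted p = 0.0496; 0.449 as adjusted p with an estimated correlation). BCL2, which blocks cell death, fell by 1.05, 1.24, 1.08 and 0.88 in clones 1, 2, 3 and 6 (SE 0.14), and so did BCL2L1, with the same role, by 0.88, 1.09, 0.45 and 0.49 (SE 0.12), and BAX, which promotes it, by 0.94, 0.83, 0.70 and 0.79 (SE 0.18). Without 1 array, the clone 3 calls of BCL2L1 (replicate 3 of clone 3 or of parental) and BAX (replicate 1 of clone 3 or replicate 3 of parental) were lost. Other splits of the same arrays called up to 6 lists. The luminal, cholesterol and BCL2 calls in clone 3 ended under several settings, leaving the mitosis list alone (1 list). The settings were renewed quantile normalization, array weights, a stricter dim filter, the 6 arrays alone and the replicate number as a block. The same calls ended without clone 1 replicate 1, which is only an example. Leaving out 1 array at a time ended list calls 34 times over all arrays and clones. Such losses are therefore not particular to that array.

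**Figure D3:**
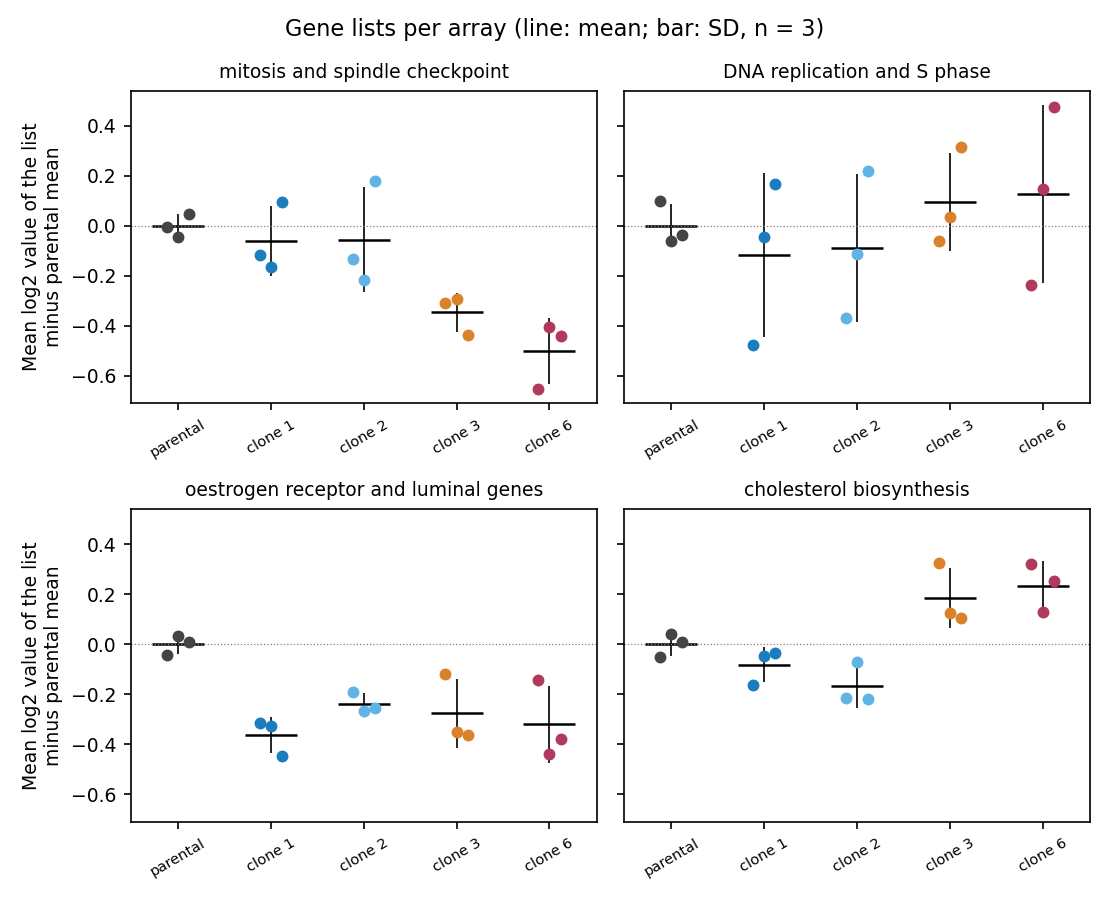
Each point is the mean log2 value of 1 gene list in 1 array minus its parental mean, by group, with lines for group means and bars for the SD (n = 3). The mitosis list lies at -0.35 in clone 3 and -0.50 in clone 6, and the S phase list varies widely between replicates of a clone (SD 0.36 in clone 6).

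Camera called none of the other 26 tested lists in any clone (adjusted p from 0.0629 to 0.992). ERBB2 itself was not analysed here; of 19 neighbours in its amplicon, 5 rose and 1 fell in clones 1 and 2, while 1 rose and 5 fell in clone 6 (6 and 1 in clones 1 and 2, 2 and 5 in clone 6, adjusted over the list alone), with GRB7, a HER2-binding adaptor, lower by 1.05 there and by 0.87 in clone 3 (SE 0.13). Of 12 HER family receptors and ligands, 5 fell and 0 rose in at least 1 clone (5 and 0 adjusted over the list alone). Of these, 1 fell in all 4 clones. ERBB4 changed by -0.75 to 0.32 (SE 0.14) and was called lower in 3 clones. ERBB3 changed by 0.18 to 0.28 (SE 0.12) and EGFR by -0.14 to 0.16 (SE 0.14), neither past the test in any clone. NRG1 and LAMP1 were not called either. Among 20 lysosomal proteases, CTSC fell by 0.74, 1.02, 1.16 and 1.18 in clones 1, 2, 3 and 6 (SE 0.11) and TPP1 by 0.94, 0.86, 0.63 and 1.16 (SE 0.09). CTSB rose by 0.36 in clone 1 and 0.46 in clone 2, CTSD fell by 0.49 in clone 3 and 0.42 in clone 6, and CTSL was not called. The call of CTSB in clone 1 was lost without its replicate 1 or any 1 parental array (0.26 to 0.37), and that of CTSD in clone 6 without parental replicate 3 (-0.37). Of the MAPK and PI3K feedback genes, IRS1, an insulin receptor substrate, fell by 1.15, 1.09, 1.10 and 1.54 (SE 0.24). EGR1 fell by 1.64, 1.63, 1.66 and 2.03 with a parental SD of 1.45, and without parental replicate 2 its changes of -0.84, -0.83 and -0.85 in clones 1, 2 and 3 were not called. A dimmer probe set of EGR1 changed by -0.17 to -0.42, and with the mean of both the call in clone 2 was lost (-0.90, adjusted p = 0.0591).

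**Figure D4:**
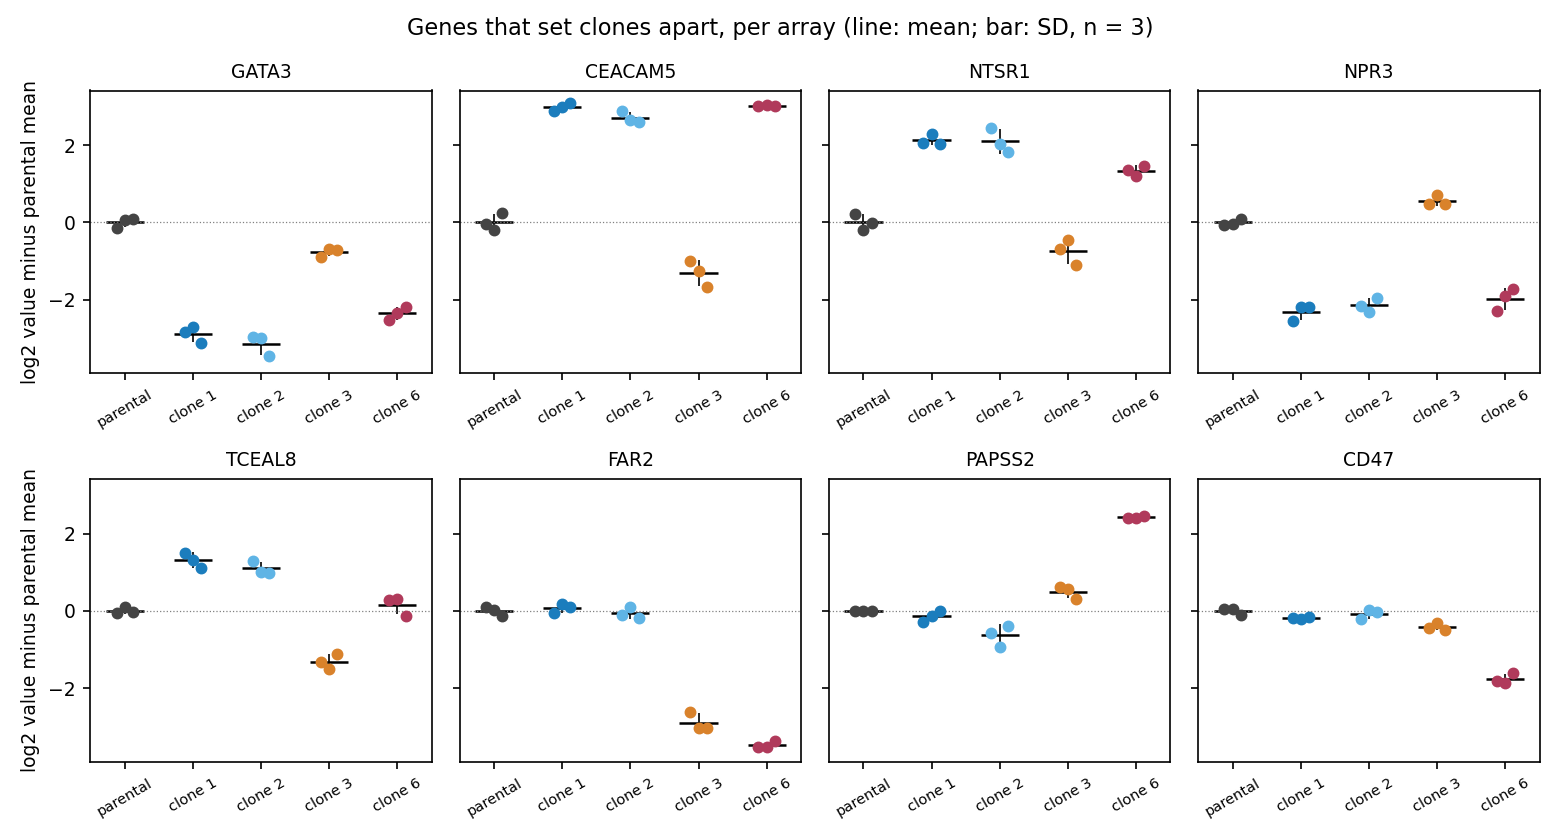
Each point is the log2 value of 1 gene in 1 array minus its parental mean, by group, with lines for group means and bars for the SD (n = 3). CEACAM5 is higher by 2.72 to 3.03 in clones 1, 2 and 6 and lower by 1.31 in clone 3, on the log2 scale.

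Compared with each other, clones 1 and 2 showed no called gene in limma, although 807 of 12147 genes had an unadjusted p below 0.05. Other settings called at most 6 genes. The F test called 2728 genes as different among the 4 clones. Pairs with clone 3 or clone 6 differed in 2041 (clones 1 and 3), 1914 (clones 2 and 3), 1540 (clones 1 and 6), 1356 (clones 2 and 6) and 1095 genes (clones 3 and 6), and the difference between clones 1 and 6 dropped to 1014 genes without clone 6 replicate 3. Set apart from the parental line and from all other clones were 89 higher and 157 lower genes in clone 3 and 90 higher and 145 lower genes in clone 6. In clone 3 these included GRAMD2A (1.27), CRACR2A (1.17) and LPAR3, a receptor for lysophosphatidic acid (1.01), as higher genes, and TCEAL8 (-1.32) and PMAIP1, which promotes cell death (-1.40), as lower genes. In clone 6 they included APOD (2.20), LRRC31 (1.72) and NXN (1.78) as higher genes and ELF4 (-1.81) and ANKRD30A (-1.66) as lower genes. CEACAM5 differed between clones 3 and 6 by -4.34 (clone 3 minus clone 6, log2).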

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

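Of the tests in this part, those of the S phase list and of the sign of the mitosis genes were chosen only after the result was seen. Single arrays were not tested as outliers within their groups of 3.

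Some results differed between clones in a direct test (camera, adjusted p below 0.05; medians of log2 differences, first clone minus second). The mitosis and spindle checkpoint list differed by 0.25 between clones 1 and 3, 0.41 between clones 1 and 6, 0.26 between clones 2 and 3 and 0.40 between clones 2 and 6. Cholesterol biosynthesis genes differed by -0.21, -0.27, -0.32 and -0.35 for the same pairs. The ERBB2 amplicon list differed by 0.22 between clones 1 and 6 and 0.18 between clones 2 and 6, and the MAPK and PI3K feedback list by 0.17 between clones 1 and 3 and 0.20 between clones 2 and 3. Between clones 2 and 6 the interferon list differed by 0.14 and the ribosomal protein list by 0.17. Between clones 1 and 2 the luminal list differed by -0.0699 and the ribosomal protein list by -0.0734. With an estimated correlation none of these differences was called (lowest adjusted p = 0.163).

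Some named genes rose in 1 clone and fell in another, with the direct test passed (largest log2 difference, first clone minus second). Clone 1 minus clone 3 was 2.89 for NTSR1, 2.63 for TCEAL8, 1.06 for B2M, -2.88 for NPR3 and -1.44 for THBS1. Clone 2 minus clone 3 was 2.21 for PMAIP1, 1.35 for AXL and -4.16 for TARP. Clone 1 minus clone 6 was 1.23 for OPTN, clone 2 minus clone 6 was -3.06 for PAPSS2, and clone 3 minus clone 6 was -4.34 for CEACAM5. In clone 3 the change of NPR3 was not called without its replicate 2 (0.49), nor that of PAPSS2 without its replicate 1 or 2 (0.44 to 0.46). Those of B2M (-0.45 to -0.39), AXL (-0.37 to -0.35) and THBS1 (0.36 to 0.45) were not called without any 1 of several arrays, parental replicate 1 among them. With the mean of its probe sets B2M changed by -0.28 in clone 3 and was not called (adjusted p = 0.0953).

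Probe sets without a gene symbol, which no comparison above used, also differed: 27 were higher and 67 lower by at least 2-fold in all 4 clones, out of 21751 tested.

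Of 41 mitosis genes 16 fell in clone 3 and 25 in clone 6, and camera called the list in both, though not with an estimated correlation (adjusted p = 0.951 and 0.679). A few dominant genes would not account for this, since at least 37 of the 41 members lay below 0 in each of these clones, although the share called lower, 39.0% in clone 3 and 61.0% in clone 6, reached the bound set beforehand in clone 6 and missed it in clone 3. A single array would not either, as the list median stayed at or below -0.28 whichever array was left out. A smaller share of cycling cells would lower S phase genes too. The lower median of that list was 0.12, but it was -0.0212 in clone 3 and -0.0656 in clone 6 without their replicate 3. The test therefore cannot tell whether a smaller share of cycling cells lies behind the fall. Of its 25 members, 1 in clone 3 and 0 in clone 6 lay below the mitosis median. That would argue against a smaller share only if both lists react alike to it, which was not tested. A different spread of cells over the phases of the cycle, for which the mitosis mean minus the S phase mean (at most -0.25 in the 6 arrays of these clones, at least -0.10 in parental arrays) leaves room, and a direct effect of the drug if it was present at harvest, may each be involved and were not tested.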

How the results depend on the processing

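No named gene or list called in a clone changed direction under any alternative. Of 497 calls of named genes in a clone, 102 were lost on leaving out at least 1 array, 99 at an adjusted p below 0.01, 24 with quantile normalization again, 17 with the 6 arrays alone, 12 with no filter on dim probe sets, 9 with arrays centred on their median, 6 with trend and robust eBayes, 3 with the mean of all probes of a gene, 3 with the replicate block and 1 with array weights. Where a count changed, the cause was not tested unless stated.

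At an adjusted p below 0.01, the genes changed against parental were 1051, 1079, 1018 and 1556 in clones 1, 2, 3 and 6, and 1548 differed among the clones. At that level clone 1 differed from clone 3 in 1073 genes and from clone 6 in 746, clone 2 from them in 1033 and 687, and clone 3 from clone 6 in 522. Array weights gave 3448 genes in clone 1.

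On leaving out 1 array, the genes changed ranged from 1229 (without parental replicate 3) to 2241 (without clone 6 replicate 1) in clone 1, from 1265 to 2224 in clone 2 and from 1275 to 2243 in clone 3 (without the same arrays). In clone 3 the count was 1368 without parental replicate 2. Between clones 1 and 6 it ranged from 1014 (without clone 6 replicate 3) to 1599 (without clone 2 replicate 1).

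Between clones 1 and 2, where no gene was called, array weights gave 4 genes, the mean of all probes of a gene 2, trend and robust eBayes 5, quantile normalization again 6 and the replicate block 6. Leaving out 1 array gave 0 to 1. The labels do not say that a replicate number marks a shared day. Of 30 pairs of arrays with the same number in different groups, 10 had correlated deviations above 0.1 (from -0.129 to 0.462 over all pairs). Each of these 10 joined 2 clones, while pairs of a parental and a clone array lay between -0.129 and 0.069. The S phase list rose from replicate 1 to 3 in all 4 clones. The clone arrays may thus share handling that the parental arrays lack, which was not tested.

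List calls were less stable. In clone 1 the fry self-contained test called 8 lists, no filter on dim probes 1, the 6 arrays alone 2, and leaving out 1 array 0 to 2. In clone 2 fry called 12 and leaving out 1 array 0 to 1. In clone 3 camera with an estimated correlation called 0, while array weights, the filter at the 60th percentile, quantile normalization again, the replicate block and the 6 arrays alone each called 1, the mitosis list, and leaving out 1 array 1 to 4. In clone 6 camera with an estimated correlation called 0, fry 18, array weights 4, no filter on dim probes 4, and leaving out 1 array 2 to 5.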

Other observations

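The tests of a shared origin of clones 1 and 2, of variation between replicate arrays along the chromosomes, and of the places of the shared genes were chosen only after the results were seen.

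Several genes that moved in all 4 clones are neighbours in the order of tested protein-coding genes (GRCh38 gene table). CXCR4 and MCM6 are next to each other (1 place apart) and NCKAP5 lies 7 places from MCM6; GPX2 and PLEK2 are 3 places apart. These make 4 pairs within 25 places among 12 placed higher genes, which 1 of 1000 random sets of genes reached. Of 13 placed lower genes 1 pair was so close, FSTL5 and NPY1R at 2 places, which 305 of 1000 random sets reached. FAR2 and TMTC1, both strongly lower in clones 3 and 6, are 2 places apart as well. Stretches of 25 neighbouring genes moved together: from TMOD3 to TLN2 the median was -0.56 in clone 3, with 18 genes called lower and 0 higher, -0.23 in clone 6, -0.0769 in clone 2 and -0.0231 in clone 1; from ULBP3 to WTAP it was -0.49 in clone 3, with 16 called lower, and between -0.0460 and -0.0181 in the other clones. From PAM to DMXL1 it was 0.41 in clone 3, with 13 called higher and 2 lower, and between -0.0986 and 0.00758 in the other clones. From TNRC18 to SNX13 the median was -0.38, -0.46, -0.24 and -0.50 in clones 1, 2, 3 and 6. The largest median in 200 shuffled gene orders was 0.353, 0.360, 0.391 and 0.474 in size in these clones. Shuffled orders were scanned at only some of the starts used in the real order, so these limits tend to be too low. Narrow excesses, such as PAM to DMXL1 in clone 3 and TNRC18 to SNX13 in clones 1 and 6, are not shown to go beyond chance. Other falling stretches were ZNF689 to KRABD5 in clone 2 (-0.64), and ZNF48 to KAT8 (-0.48) and EPDR1 to OGDH (-0.47) in clone 1. ZNF175 to ZNF600 in clone 6 (-0.52) passed narrowly. The highest rising stretches of clones 1, 2 and 6 (0.352, 0.253 and 0.382) did not exceed the limits. Nor did that from IWS1 to CXCR4, at 0.34 in clone 3, 0.21 in clone 6, 0.0828 in clone 2 and 0.0334 in clone 1.

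Other lists moved in parts. Among 18 hypoxia and glycolysis genes 7 rose and 3 fell in at least 1 clone (7 and 3 adjusted over the list alone), and HK2, hexokinase 2, rose by 0.60 to 0.87 in all 4 (SE 0.11). Among 26 oxidative stress and xenobiotic genes 9 rose and 6 fell (11 and 7 adjusted over the list alone), with GSTA4 higher by 0.63 to 1.06. Of 16 mesenchymal transition genes 3 rose and 7 fell (3 and 7 adjusted over the list alone), with TWIST1 lower by 0.54, 0.67, 1.06 and 1.10 in clones 1, 2, 3 and 6; its call in clone 1 was lost without any 1 of 4 arrays, parental replicate 3 among them (-0.52 to -0.42). Among 22 interferon response genes 1 rose and 8 fell in at least 1 clone (1 and 8 adjusted over the list alone). HERC5 and HERC6 fell by 1.32 and 1.22 in clone 3 and by 1.47 and 1.31 in clone 6. The only gene that rose was MX2, 2.93-fold and 3.04-fold in these clones. HERC6 also fell by 0.58 in clone 1, which was not called without clone 1 replicate 1 or 3 or parental replicate 2 (-0.55 to -0.47). Of the ribosomal proteins RPS28 fell by 0.72 to 0.89 in all 4 clones (SE 0.09), and of the autophagy genes MAP1LC3A fell by 0.82 to 1.61 (SE 0.17). Of the lists for other cell types, the fibroblast and leukocyte lists had no called gene in any clone (0 of 5 and 0 of 10), and 2 of 9 endothelial genes fell.

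No gene was called between clones 1 and 2, and other settings called at most 6. A spread too large to see many differences of 2-fold or more is argued against by simulated clones with their spread. In these, with 200 genes changed, 0.907 of 2-fold but 0.537 of 1.5-fold differences were recovered. Fewer or smaller differences could therefore be missed. Arrays mixed between these labels are argued against as well, since the other splits of their 6 arrays called at most 1 gene. The standard deviation over genes of their log2 difference was 0.571 of that of the closest other pair (0.159 against 0.279). Array spread alone, pooled over all 5 groups, would give 0.150, and pairing arrays with the same replicate number 0.133. The root mean square SD within groups was 0.193 and 0.202 in clones 1 and 2 but 0.142 in parental arrays, which lowers the pooled value. An excess over the unpaired spread of these 2 clones is therefore not shown. With the replicate block 6 genes differed. A shared origin, with clones 1 and 2 as descendants of the same resistant cell, is a candidate explanation that leaves room for small differences. Any cause that makes these clones alike would give such values, so they do not single out a shared origin. The history of the clones was not tested.

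Log2 changes of neighbouring genes were correlated in every clone. Overlapping neighbours that share probes would not reach genes 10 places apart, where the lowest of the 4 correlations was 0.0502, above each of 1000 shuffled orders. Duplicated genes that share probes could lie that far apart or further, so this distance cannot exclude them. Variation between replicate arrays gave at most 0.180 of the covariance at that distance in the clones against parental. The log2 difference between clones 1 and 2, which held no called gene, also correlated, at 0.0575 for 10 places and 0.0245 for 50. It was not set against shuffled orders or replicate arrays. Whether correlated neighbours are particular to comparisons with the parental line is therefore left open, and the cause was not tested. Copy number differences may contribute, but 50 places apart the correlations of clones 3 and 6 (0.0865 and 0.0563) passed all shuffled orders and those of clones 1 and 2 (0.0340 and 0.0354) did not, so the array values leave this open. DNA was not measured here.

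Other splits of the arrays were run for every count. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For genes changed against parental, the real split gave 2092, 2058, 2090 and 2724 in clones 1, 2, 3 and 6 and 145, 167, 164 and 266 at least 2-fold, and the highest other split gave 0; only 1 split, the real one, was as large each time. For gene lists, 10, 10, 4 and 9 of the 10 splits called as many lists as the real 0, 0, 4 and 2, and the highest others called 5, 5, 6 and 6, so mixed groups of these arrays yield list calls as well. Between clones 1 and 2 all 10 splits called as many genes as the real 0 (highest other 1), and for the other 5 pairs 1 split did, with 0 or 1 as the highest other. For the 2728 genes that differ among the clones, 1 of 100 regroupings, the real one, was as large (highest other 707). A random assignment of clone arrays to clones is thus argued against for that count at the level of 0.05. For the 7 higher and 24 lower genes at least 2-fold in all clones it was also 1 of 100 (highest other 0). Those regroupings mixed parental and clone arrays, which widens the spread within groups and leaves few calls. They argue against arrays without any group structure, and cannot tell whether the sharing between clones goes beyond chance or shared parental errors.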
